A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

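Affymetrix rice genome arrays were used by the authors to measure RNA from developing rice seeds (Oryza sativa Japonica Group). Per the labels, 3 biological replicates came from plants that received 400 mg of ammonium chloride per container at heading, and 3 came from plants without it. All plants had been fertilized at planting and again 37 days after germination, and seeds were selected from 6 plants. The labels do not say whether the replicates of a group came from separate plants, so p-values measure the spread between these samples, which could be partly technical. The source label gives 15 days after flowering for the additional NH4Cl samples, and the day of the control samples is not given in the sources used here. The tissue label says developing seed while the extraction label speaks of seedlings, and the tissue label is followed here. RNA was extracted with an RNeasy plant kit and labelled as biotinylated cRNA, per the labels' protocols.

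The deposited table holds 1 value for each of 57381 probe sets on each of 6 arrays, with 9 decimals. The deposited values were read as log2 expression, from their range of 4.96 to 13.51; the base, the summarization and the normalization are not given in the sources used here. Per the table itself, the arrays had almost the same distribution, with medians that differed by at most 0.00015, and differences between arrays were very small: the median SD of a rice probe set over the 6 arrays was 2.2e-06, 97.4% of them had an SD under 0.001, and 12 had an SD over 0.1. A difference in this table is therefore not a log2 fold change of RNA. Differences are given in the deposited log2-scale units and, beside them, divided by the within-group SD of the same probe set. That ratio does not depend on the scale of a probe set's values. No array shared more than 41 values with another, so no array was counted as a duplicate. The small number of arrays also limits the precision.

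The 187 Affymetrix control probe sets were left out of the tests, which covered 57194 rice probe sets without a filter on dim ones. Additional NH4Cl minus control was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust, no block), with two-sided p-values and Benjamini-Hochberg adjustment at 0.05. Standard errors printed beside differences are the unmoderated ones. Probe sets were named through the platform annotation and a gene table of assembly ASM3414082v1: 22436 probe sets had 1 gene, 95 had several and 34663 rice probe sets were unnamed here. The 22436 probe sets stood for 17905 genes, of which 2457 (13.7%) had a name other than a locus number. No coordinates are given, because the authors' build is not known.

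The tests, the gene lists and the rule for named genes were fixed before the data were examined. The planned lists used product descriptions and locus identifiers that the tables did not hold, so 26 lists were rewritten as patterns on gene names, with 416 genes, after the tables of genes were seen and before any group was compared. The merged list of seed storage proteins was added at that point, and several lists gained related genes, among them subunits of protein glycosylation, ER-resident J proteins and ER stress regulators, seed tonoplast intrinsic proteins and origin recognition proteins. Each gene was represented by its probe set with the highest mean. Lists of at least 4 genes were tested with limma's camera (preset correlation 0.01), with an estimated correlation beside it, and lists below that size were given as values. The cellulose synthase list is one that the published study of these arrays reported on, so it is not independent evidence of direction.

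The rule named, among probe sets at adjusted p under 0.05 with 1 named gene, a mean at or above the median of 5.718 and non-overlapping groups, up to 12 per direction, or the 8 with the smallest p where none passed; and per list up to 4 members past the threshold, or the 2 with the highest mean. A described product was read as an informative gene name, since the tables hold no descriptions. Genes that passed only when adjusted over the list alone, and the largest differences, were named after their values were seen. Probe sets that can hybridize with several transcripts are named as uncertain.

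The alternatives were the replicate number as a block, eBayes with trend and robust, rank products over the 9 pairs of arrays with 100 permutations, a test with unequal variances, quantile normalization and median centring of the arrays, filters on level, removal of cross-hybridizing probe sets, a 2-fold minimum and each array left out; the lists were also tested with fry and with the mean of each gene's probe sets. Median centring added 0.000123 to the median difference, so by construction it turns most smaller negative differences positive; the same amount adds less to the t of a probe set with a larger SD, so the list test after centring also depends on the SDs. Alternatives with another pseudocount did not apply to log values. After quantile normalization the values were rounded to 9 decimals, and differences below that precision were set to 0. This step was added after the values were seen, because 10886 probe sets then had the same value on every array. The count of calls was 4079 with and without it. Quantile normalization gives equal values to equal ranks, so a probe set that kept its rank on every array has a difference of 0 by construction. A probe set that changed rank takes the value of its new rank. That can move it by more than its deposited difference: UAM1 went from 5.46e-06 to -0.000738. A sign or call lost after this step therefore does not by itself speak against a difference.

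The fits were tested on simulated data with the real SD of each of the 57194 probe sets. With no group difference, limma made 0 adjusted calls and 2793 probe sets had an unadjusted p under 0.05. Of 50 probe sets shifted by 4 within-group SDs limma recovered 2%, of 50 shifted by 8 SDs 30%, and of 50 shifted by 16 SDs 96%. Rank products made 195 higher and 170 lower calls with no difference present, so their calls are given as a count and not by gene.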

Results

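Gene expression was compared in developing rice seeds between 3 arrays from plants given ammonium chloride at heading, called additional NH4Cl, and 3 arrays from control plants. The series asks how additional fertilization changes expression in the seed. Array medians of the deposited log2 values lay between 5.71845 and 5.7186.

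Cytosolic ribosomal proteins, the protein part of the translating ribosome, were higher with additional NH4Cl for 25 of 26 genes. After quantile normalization 13 of 26 were higher. Of the rest some, among them RPS21, Ub-CEP52-1 and RPS27AA, had no difference left, and some were lower, among them RPS3A at -0.000724 and RPS10-1 at -4.19e-05. Genes of amino acid biosynthesis were higher for 21 of 29. Genes for cell wall glycans other than cellulose were lower for 32 of 44, and those of DNA replication and cyclins for 23 of 29, and both lists' medians turned positive when arrays were centred on their medians, which by construction raises nearly all probe sets. At the level of single probe sets limma called 4 of 57194, all lower with additional NH4Cl, and 0 higher. One of these is OsTERT, the telomerase reverse transcriptase, with a difference of -8.55e-06 (SE 2.366e-07, n = 3 per group; -29.5 within-group SDs), which was positive after median centring. OsTERT had a mean of 5.94 in both groups, below a reporter control probe set at 6.07, so its signal need not come from its RNA. At an unadjusted p under 0.05, 2914 probe sets were higher and 3411 were lower. A test with unequal variances called 0 after adjustment, with 2124 higher and 2469 lower at an unadjusted p under 0.05.

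The other called probe sets belonged to LOC4340672, LOC4337207 and LOC4326137, named after their values were seen because so few passed. Their differences were -0.0106, -0.0366 and -0.000138, and that of LOC4326137 turned positive after quantile normalization. The control means of LOC4340672 and LOC4337207, 5.90 and 5.73, also lay below a reporter control probe set at 6.07. LOC4340672 and LOC4337207 stayed lower and passed after quantile normalization (adjusted p of 0.000143 and 0.000115) and after median centring (0.00196 each). Those scalings called 4079 and 51354 probe sets. All 4 probe sets called as deposited had an adjusted p of 0.0458 with limma. None of the 4 passed in any fit with 1 array left out, where OsTERT had adjusted p between 0.0995 and 0.272. Those fits made 1 call without control replicate 1, 1 without control replicate 3 and 0 without any other array. With probe sets below the median level removed there were 32 calls, 12 higher and 20 lower, and rank products made 1385, a method that also made calls on simulated data without a difference.

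The 8 named genes with the smallest p among the higher ones did not pass, with adjusted p between 0.111 and 0.129. They were HSP18.0, LIR1, RPS3A, HAP5B, APR-like1, MT-2, APX1 and 60SP0. APR-like1 had a difference of 0.0093 (SE 0.00103; 7.35 within-group SDs), and APX1, a cytosolic ascorbate peroxidase that removes hydrogen peroxide, one of 0.000278 (SE 3.24e-05; 6.99 SDs). The heat shock gene HSP18.0 stood at 1.41e-05 (8.54 SDs) and LIR1, a light-regulated gene, at 7.95e-06 (7.97 SDs), the latter negative after quantile normalization as were RPS3A and MT-2. LIR1 had a mean of 6.03 in both groups, below a reporter control probe set at 6.07.

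Ribosomal protein genes had a median t of 3.18, which was 0.18 after quantile normalization and 4.92 after median centring, and the list passed camera with an adjusted p of 1.62e-12. With an estimated correlation of 0.254 between its genes the adjusted p = 0.155. None of its genes passed over all probe sets and 11 passed adjusted over the list alone, all higher. RPS3A had a difference of 6.74e-05 (SE 7.14e-06; 7.71 SDs), 60SP0 of 0.00124 (SE 0.000146; 6.89 SDs) and RPS7 of 0.00469 (SE 0.000839; 4.57 SDs), each higher on 3 of 3 arrays than the control mean; RPS3A alone of these was negative after quantile normalization. RPS21 and Ub-CEP52-1, the members with the highest signal, had differences of 7.49e-06 and 5.35e-05 and did not pass. The single exception to the direction was RPL27 at -7.25e-05, measured with an uncertain probe set. The 3 aminoacyl-tRNA ligases were too few for a test, and MetRS and LysRS stood at 5.46e-05 and 0.00041, LysRS being negative after quantile normalization.

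Amino acid biosynthesis genes had a median t of 1.5, and the list passed with an adjusted p of 0.000455 (adjusted p = 0.155 with an estimated correlation). With 12 members higher and 1 lower at an unadjusted p under 0.05, 0 passed adjusted over the list alone. The members with the highest signal were P5CS1, of proline synthesis, at 0.000134, and DAHPS2, of the shikimate pathway, at 0.00305 with an uncertain probe set. Nitrogen assimilation genes did not pass as a list (adjusted p of 0.172), with 6 of 9 higher. GDH2, a glutamate dehydrogenase, passed adjusted over the list alone with a difference of 0.00337 (SE 0.000495; 5.55 SDs), while the glutamine synthetases GLN1-3 and GLN1-2 stood at 0.000428 and -0.000109. Of 13 transporters of ammonium, nitrate and amino acids 7 were higher, with a median that turned negative after quantile normalization, and the list did not pass (adjusted p of 0.853); PROT1 stood at 0.000114 and AMT1-1 at 6.9e-07.

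**Figure D1:**
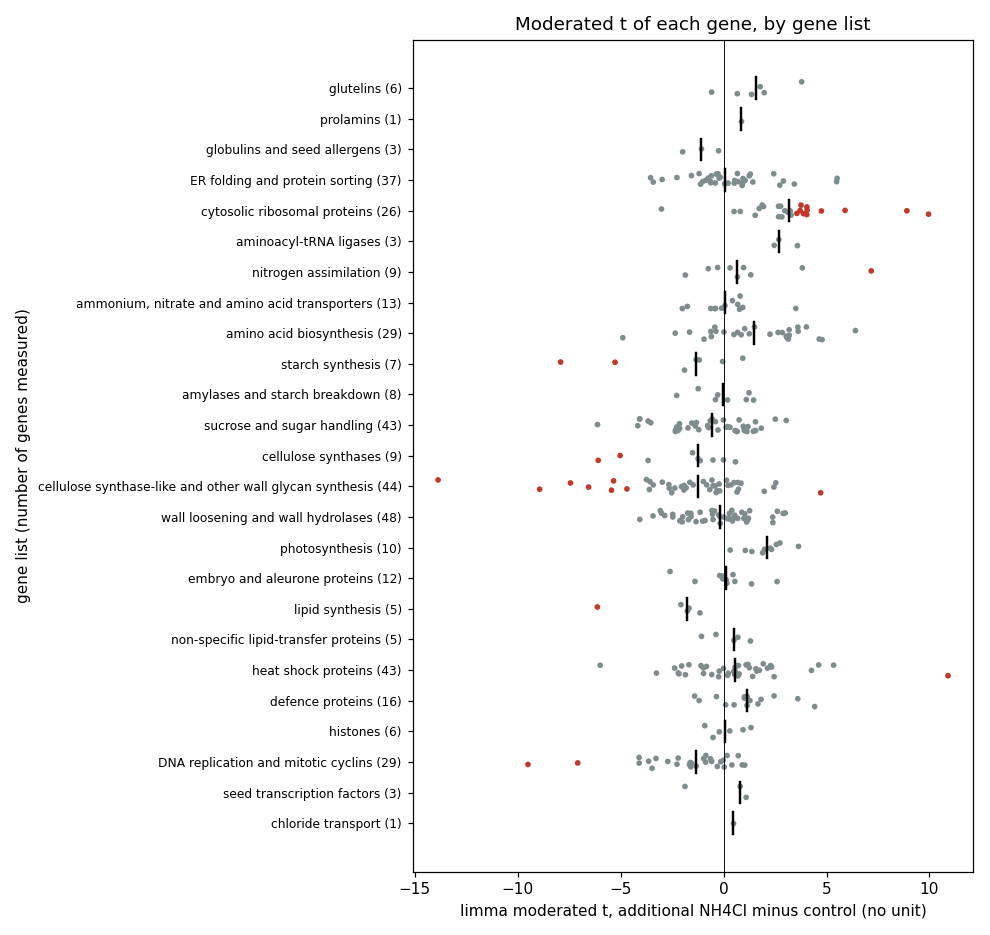
Moderated t of each gene for additional NH4Cl minus control (horizontal axis, no unit), by gene list (vertical axis, with the number of genes); each point is 1 gene, the black bar is the list median, and red marks genes that passed adjusted over the list alone. Ribosomal proteins have a median t of 3.18, or 0.18 after quantile normalization, and wall glycan genes one of -1.23, positive when arrays are centred on their medians, which raises nearly all probe sets.

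Cellulose synthases were lower for 8 of 9 genes, with a median t of -1.24 that kept its sign under quantile normalization, where the list no longer passed (adjusted p of 0.272), and median centring. The list passed camera with an adjusted p of 0.00737 (adjusted p = 0.219 with an estimated correlation), and it is not independent evidence since the study reported on it. Of its genes 2 passed adjusted over the list alone: CESA5 with a difference of -0.00341 (SE 0.000591; -4.72 SDs) and CESA8 with -0.000905 (SE 0.00019; -3.89 SDs). CESA1 and CESA3, the members with the highest signal, stood at -0.000132 and -3.11e-05, CESA3 being positive after median centring. Leaving out additional NH4Cl replicate 1 or control replicate 2 ended the list's call, with adjusted p of 0.0792 and 0.0565.

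The list of cellulose synthase-like and other wall glycan genes had a median t of -1.23, positive after median centring, and passed with an adjusted p of 9.27e-05 (adjusted p = 0.0882 with an estimated correlation). It did not pass after quantile normalization (adjusted p of 0.123), and was lower relative to other genes after centring (adjusted p of 3.27e-16), a test that depends on the SDs. Of 44 genes 8 passed adjusted over the list alone, 7 of them lower. They include CSLF6, a synthase of mixed-linkage glucan, with a difference of -0.00651 (SE 0.00146; -3.64 SDs), CSLA5, of a glucomannan synthase family, with -0.00223 (SE 0.000316; -5.76 SDs), and UGE-2, which interconverts UDP-glucose and UDP-galactose, with -0.0103 (SE 0.00165; -5.08 SDs). CSLD5 was the higher one at 2.34e-06. CSLC7, CSLA1, CSLC9 and CSLA7 were the other lower ones, CSLC7 with an uncertain probe set, CSLC9 positive after quantile normalization and CSLA7 after median centring. CSLC7, at a mean of 5.87, and CSLD5, at 5.57, lay below a reporter control probe set at 6.07. UAM1 and IRX14, with the highest signal, stood at 5.46e-06 and, with an uncertain probe set, 9.27e-07, both negative after quantile normalization. The 48 wall loosening genes did not pass (adjusted p of 0.394), with OsCel9D at -0.00031 and OsGLU2 at -0.000503.

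Starch synthesis genes were lower for 6 of 7, with a median t of -1.33 that turned positive after median centring, and the list passed with an adjusted p of 0.0158 (adjusted p = 0.166 with an estimated correlation). It did not pass after quantile normalization (adjusted p of 0.829, with a median t of 0), and was lower relative to other genes after centring (adjusted p of 0.000738). SSI, a soluble starch synthase, had a difference of -0.0289 (SE 0.00385; -6.13 SDs), its means being 9.86 ± 0.0043 with additional NH4Cl and 9.89 ± 0.0051 in control (SD, n = 3 each). AGPS2, a subunit of ADP-glucose pyrophosphorylase, stood at -2.52e-05 (-4.09 SDs), positive after median centring and with no difference left after quantile normalization. Both SSI and AGPS2 passed adjusted over the list alone. Sbe1 and GBSS1, with the highest signal, stood at -1.33e-07 and, with an uncertain probe set, -1e-06. The call ended without control replicate 1 or 2, at adjusted p of 0.0504 and 0.054. Amylases did not pass (adjusted p of 0.985), with DPE2 at -0.000155 and AMY1.4, on an uncertain probe set, at 0.00761; the list's median and mean t were negative while the test's direction was up. Sucrose and sugar genes did not pass (adjusted p of 0.0878), with 25 of 43 lower and a median that turned positive after median centring. The transporter SWEET11, on an uncertain probe set, stood at -1.19e-05 and SUS4 at -2.79e-05. All 5 lipid synthesis genes were lower as deposited, with a median t that turned positive after median centring (adjusted p of 0.00721, and adjusted p = 0.155 with an estimated correlation). They did not pass after quantile normalization (adjusted p of 0.883), and were lower relative to other genes after centring (adjusted p of 0.000197). DGAT1-1, which makes triacylglycerol, had -0.000147 (-4.75 SDs) and passed adjusted over the list alone, while SSI2 stood at -3.52e-05.

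The glutelins were higher for 5 of 6 genes, with a median difference of 2.16 SDs, and did not pass (adjusted p of 0.055). Quantile normalization left no difference in any of the 6, which probe sets that keep their rank give by construction. GLUA-2 had a mean of 13.21 and a difference of 1.4e-07 (1.37 SDs), and GLUB-5 one of 4.13e-07 (4.28 SDs). The single named prolamin gene stood at 1.7e-07 (2.37 SDs), and its mean of 13.50683 was the maximum of the arrays. The allergens RA14 and RA5 stood at -7.67e-08 (-0.242 SDs) and -3.97e-07 (-7.91 SDs), both positive after median centring. These probe sets lay at or near the top of the signal range, which limits the change they could show. GLUA-2, prolamin, RA14 and RA5 were measured with uncertain probe sets. The 3 storage lists together did not pass (adjusted p of 0.35). Genes of protein folding and sorting in the endoplasmic reticulum were higher for 19 of 37 (adjusted p of 0.605), with the chaperone BIP1 at 7.45e-05 (4.25 SDs) and the disulfide isomerase PDIL1-1 at 0.000446 (2.66 SDs), both short of the threshold. NFYB1 and MADS29, seed transcription factors, stood at 2.92e-06 and -7.94e-05.

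**Figure D2:**
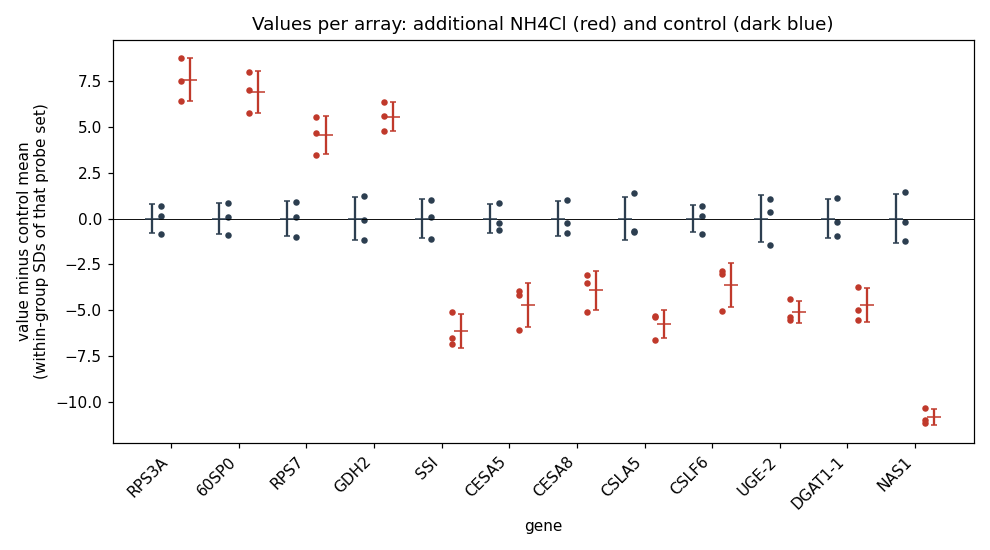
Values per array for 12 genes, chosen after their values were seen, as the value minus the control mean in within-group SDs of that probe set (vertical axis); points are arrays, red for additional NH4Cl and dark blue for control, and bars are means with SD (n = 3 each). The groups do not overlap in any of these genes, with a difference of 7.71 SDs in RPS3A, which is negative after quantile normalization, and of -6.13 SDs in SSI.

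All 10 photosynthesis genes, markers of green tissue such as the pericarp, were higher, with a median t of 2.13. The list passed with an adjusted p of 0.000471 (adjusted p = 0.289 with an estimated correlation). After quantile normalization 5 of 10 were higher, with a median t of 0.52, and the list did not pass (adjusted p of 0.435). After median centring the median t stayed positive while the list's direction relative to other genes reversed. CAB2R stood at 0.000738 and PETE at 0.000457. Embryo and aleurone proteins did not pass (adjusted p of 0.853), with RAB21 at -1.51e-05 and TIP3-1, on an uncertain probe set, at 3.4e-07, and neither did the lipid-transfer proteins (adjusted p of 0.853), with LTP-2 at -2.24e-05 and LTP, also uncertain, at 4.36e-05. Defence proteins were higher for 13 of 16 (adjusted p of 0.0189, and adjusted p = 0.219 with an estimated correlation). After quantile normalization 11 of 16 were higher, with a median t of 0.826, and the list did not pass (adjusted p of 0.249). After median centring the median t stayed positive while the direction relative to other genes reversed. The chitinase Chib3H-h stood at 0.000363 and RBBI3.3, on an uncertain probe set, at -0.000139. The list's call ended without additional NH4Cl replicate 2 or control replicate 1, at adjusted p of 0.0507 and 0.156.

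DNA replication and cyclin genes had a median t of -1.33, positive after median centring, and passed with an adjusted p of 0.000132 (adjusted p = 0.0882 with an estimated correlation). The list did not pass after centring (adjusted p of 0.661) or quantile normalization (0.435). PCNA, the replication clamp, at -1.73e-05 (-7.4 SDs) and CYCA3-2 at -2.23e-05 (-5.5 SDs) passed adjusted over the list alone, both positive after median centring. CYCA3-2 had a mean of 5.96 in both groups, below a reporter control probe set at 6.07. CYCD5-2 and CYCD5-3, with the highest signal, stood at -0.000346 and -0.00156, CYCD5-2 being positive after quantile normalization. Histones did not pass (adjusted p of 0.853), with H2B.11 at -3.65e-05 and H2B.5 at 5.97e-05. Heat shock proteins did not pass as a list (adjusted p of 0.172) with 27 of 43 higher. HSP18.0 passed adjusted over the list alone, with no difference left after quantile normalization. HSP81-3, on an uncertain probe set, and hsp17.9 stood at 4.67e-06 and 1.7e-07. The chloride transporter CCC1 stood at 5.02e-06. Of the other list members named, GLN1-2, Sbe1, GBSS1, SWEET11, SUS4, SSI2, MADS29, RAB21, LTP-2 and H2B.11 turned positive after median centring, and AMT1-1, H2B.5 and CCC1 turned negative after quantile normalization.

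In all, 9 of 21 tested lists passed camera with the preset correlation, 0 with an estimated one and 0 after quantile normalization. There those 9 had adjusted p between 0.0909 and 0.883. In that fit ribosomal genes had a mean t of 643 beside a median of 0.18, and ER folding genes a mean of -105 beside a median of 0. Calls lost there therefore do not decide whether a list shifted. Fry passed 6, of which 5 were among the 9 called lists and the other was the glutelins (adjusted p of 0.0385). The estimated correlation was -0.00364 for wall glycan, -0.0284 for DNA replication, -0.0866 for starch and -0.0824 for lipid genes. These lie below the preset 0.01, so a higher correlation between their genes is not what ended those calls. In the other called lists it ran from 0.0344 to 0.512.

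The first principal component of the scaled values held 26.5% of the variance and separated the groups, with additional NH4Cl between -182.3 and -37.33 and control between 84.69 and 131.1. The second held 24% and set additional NH4Cl replicate 3, at -217.7, apart from the other arrays. Groups of 3 did not overlap in 17.4% of rice probe sets, against 10% by chance. The share of probe sets at an unadjusted p under 0.05 was 4.65% in the lowest of 4 equal bins of signal and 19% in the highest. In a limma fit of the 187 control probe sets 0 passed adjustment. At an unadjusted p under 0.05 were 5 of 27 for rice housekeeping genes and rRNA, and 3 of 86 spike-ins and tags. So were 2 of 64 reporters and 0 of 10 fungal ones. All probe sets of the spike-ins bioB, bioC, bioD and cre (9, 6, 6 and 6) had a higher mean with additional NH4Cl. Their differences ran from 9.413e-06 to 0.002366, none at p under 0.05, beside a median difference of 0.000663 in ribosomal protein genes. The ribosomal median was 2.46 within-group SDs, and the groups did not overlap in 20 of those 26 genes. In each of these spike-in probe sets additional NH4Cl replicate 3 was the lowest of its group and lay below a control array, so the groups overlapped.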

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

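The alternatives that scaled each probe set to unit SD, required a minimal range, changed the background of the lists, applied the upper-quartile filter or the removal of cross-hybridizing probe sets to the lists, or recomputed the principal components were chosen after seeing the data. The number of called probe sets, 4 as reported, was 2 with the replicate block, 2 with trend and robust, 0 with unequal variances, 0 with unit SD, 32 at or above the median level, 23 at or above the upper quartile, 1385 with rank products, 4079 after quantile normalization (2082 higher) and 51354 after median centring (50499 higher), and 0 to 1 with each array left out. A 2-fold minimum, which the small differences of the deposited values nearly rule out, left 0, and 1 after quantile normalization or after centring. Median centring added 0.000123 to the median difference, against a median absolute difference of 1.41e-06 as deposited, which by construction gives nearly all of its calls; for the others the cause was not tested. Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.062, 0.045 and -0.077, and the block left 9 lists called. OsTERT stood at 0.000114 after centring and LOC4326137 at 0.000106 after quantile normalization.

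The 9 called lists became 0 after quantile normalization and 0 with an estimated correlation, and 7 to 12 with each array left out. In the order ribosomal, amino acid, starch, cellulose synthase, wall glycan, photosynthesis, lipid, defence and DNA replication, adjusted p was 0.0909, 0.2, 0.829, 0.272, 0.123, 0.435, 0.883, 0.249 and 0.435 after quantile normalization, and 0.155, 0.155, 0.166, 0.219, 0.0882, 0.289, 0.155, 0.219 and 0.0882 with an estimated correlation. After median centring starch (0.000738), cellulose synthase (4.49e-17), wall glycan (3.27e-16) and lipid genes (0.000197) were still called lower relative to other genes. The median t of starch, wall glycan and lipid genes was then positive. Centring gave 0.168 for ribosomal, 0.661 for amino acid and 0.661 for DNA replication genes. It gave a reversed direction relative to other genes for photosynthesis (0.651) and defence (0.534). With fry, amino acid, cellulose synthase, photosynthesis and defence lists had 0.0993, 0.189, 0.189 and 0.225. Starch had 0.0835 against 1 probe set per gene and 0.116 against those at or above the median level, where cellulose synthases had 0.0603; defence had 0.0514 at or above the upper quartile. With each array left out, adjusted p ranged from 9.92e-17 to 1.57e-08 for ribosomal, 1.67e-05 to 0.00589 for amino acid, 0.00816 to 0.054 for starch, 0.00403 to 0.0792 for cellulose synthase, 4.38e-05 to 0.00213 for wall glycan, 3.19e-05 to 0.0274 for photosynthesis, 0.00328 to 0.0399 for lipid, 0.00314 to 0.156 for defence and 4.43e-06 to 0.00228 for DNA replication genes.

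Lists that had not passed gained a call in their own direction as follows. Sucrose and sugar genes had 6.43e-07 after centring, 0.0499 at or above the median level and 0.0367 at or above the upper quartile. Wall loosening had 0.0013 after centring. After centring both lists were lower only relative to other genes, with a median t of 3.73 and 4.41. Glutelins had 0.0385 with fry, 0.0381 with all probe sets per gene and 0.0396 without additional NH4Cl replicate 3, heat shock proteins 0.0287 without that replicate, embryo and aleurone proteins 0.0295 without it too, and nitrogen assimilation 0.0344 without additional NH4Cl replicate 1. Reversals of the test's direction relative to other genes, some in the same lists, were these. After quantile normalization adjusted p was 0.996 for nitrogen assimilation, transporters, amylases, lipid-transfer proteins, heat shock proteins and histones, and 0.883 for ER folding and for wall loosening. Glutelins and the merged storage list also had 0.996, but no difference was left in them, so they had no direction to reverse. After centring it was 0.985 for ER folding, 0.205 for nitrogen assimilation, 0.305 for amylases, 0.000378 for embryo and aleurone proteins, 0.406 for lipid-transfer proteins, 0.000295 for heat shock proteins and 0.166 for histones. Amylases had 0.926 with the block, 0.851 and 0.713 with the level filters, 0.944 without cross-hybridizing probe sets, 0.996 with a minimal range and 0.88 with all probe sets per gene. Embryo and aleurone proteins had 0.951 without cross-hybridizing probe sets and 0.996 with a minimal range, and histones 0.951 without cross-hybridizing probe sets. With arrays left out, adjusted p ranged from 0.139 to 0.926 for ER folding, 0.161 to 0.89 for transporters, 0.803 to 0.89 for amylases, 0.0295 to 0.89 for embryo and aleurone proteins, 0.447 to 0.89 for lipid-transfer proteins and 0.0584 to 0.981 for histones, with the direction reversed without some of the arrays. In the array structure, the share of variance on the first component was 26.5% as reported, 41.9% after quantile normalization and 90.2% after centring. It was 30.3% and 32.5% with the level filters and 28.8% to 33.8% with arrays left out. With an array left out there are fewer components, which by itself raises the share of the first. Of 90 named probe sets 18 changed sign after centring, 13 after quantile normalization, where 32 had no difference left, and 1 to 5 with an array left out.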

Other observations

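All values in the next 2 paragraphs were chosen after the results were seen. Genes whose names begin with KIN, most of them kinesins, the motors that move along microtubules, were lower with additional NH4Cl for 26 of 30, with a median t of -2.35 that turned positive after median centring. Of 52 families of at least 8 genes sharing a name, camera passed 6, and for this one the adjusted p was 6.75e-08 (adjusted p = 0.13 with an estimated correlation, with which 0 families passed). KIN8B, on an uncertain probe set, stood at -0.0128 (SE 0.001872; -5.58 SDs) and KIN14F at -0.000871 (-4.95 SDs). The mean of KIN14F, 6.05 in both groups, lay below a reporter control probe set at 6.07, as did those of other KIN members. The MCM genes of the replicative helicase, most of which also stand in the DNA replication list, were lower for 6 of 8 with a median t of -2.24, positive after both scalings.

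The largest differences in the table did not pass adjustment as deposited. After quantile normalization those given here passed with adjusted p between 0.00352 and 0.0347, except ADC1 (0.0804). After median centring each had 0.00759. GLUA-2, with a deposited difference of 1.4e-07, had that same value, so it does not single these probe sets out. The widest on the higher side were at a pair of probe sets unnamed here, with 1.04 (SE 0.1025; adjusted p of 0.112) and, on an uncertain probe set, 0.31. On the lower side LOC4347695 stood at -0.62 (SE 0.09229; adjusted p of 0.16) and LOC4338117 at -0.27. Among named genes the widest were ADC1, an arginine decarboxylase of polyamine synthesis, at 0.19 (SE 0.0426; adjusted p of 0.241), and NAS1, a nicotianamine synthase of metal transport, at -0.18 (SE 0.0139; -10.8 SDs; adjusted p of 0.0919).

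Of the tests that follow, those on the number of probe sets and lists, on control probe sets and on seed age were chosen after the result was seen. The list tests had been run before the predictions for these tests were written. The ribosomal, wall glycan and DNA replication lists had the smallest adjusted p in camera (1.62e-12, 9.27e-05 and 0.000132). Their percentiles and splits are therefore not independent of those calls. Ribosomal protein genes were higher as a group with the preset correlation, and not past the threshold with an estimated one (adjusted p = 0.155), after quantile normalization (0.0909, with the median t at 0.18 instead of 3.18) or after median centring (0.168). A shift that depends on signal level alone is argued against for the values as deposited. The list's median t stood at percentile 100 among 10000 random lists matched on mean level, whose median was -0.0473. Those lists were drawn gene by gene, without the list's estimated correlation of 0.254, and were not matched on SD. A shift tied to the SD therefore stays open. Quantile normalization removes by construction the difference of a probe set that keeps its rank, and what else it removed stays open. Photosynthesis genes, markers of green tissue, were higher too for 10 of 10 (adjusted p of 0.000471, and adjusted p = 0.289 with an estimated correlation). After quantile normalization 5 of 10 were higher, and the list did not pass (adjusted p of 0.435). Another share of seed parts stays open. Younger seeds in the additional NH4Cl group could give higher ribosomal genes, and would give higher DNA replication and cyclin genes, whose median t was -1.33; with an estimated correlation that list did not pass, and the controls' day is unknown, so seed age and fertilization, which stays open and untested, cannot be told apart. The 10 splits of 6 arrays are too few for a share under 0.05; 1 of them, the real one, gave a median t as large, 3.18 against at most 1.37 in the others.

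Wall glycan genes were lower as a group with the preset correlation, with a median t of -1.23 that turned positive after median centring, where the list stayed lower relative to other genes (adjusted p of 3.27e-16), and not past the threshold with an estimated correlation (adjusted p = 0.0882) or after quantile normalization (0.123). A shift that depends on signal level alone is argued against for the values as deposited, with a percentile of 0.05. The random lists were not matched on SD, so a shift tied to the SD stays open. Among the other called lists, given after their values were seen, starch, cellulose synthase and lipid genes stood at percentiles 4.69, 6.98 and 5.55. For those lists a shift by level is not argued against. Amino acid, photosynthesis, defence and DNA replication genes stood at 100, 99.9, 99.8 and 0.17. For wall glycan genes the real split, 1 of 10, had an absolute median t of 1.23 against at most 0.708. For DNA replication and cyclin genes 1 of 10 had 1.33 against at most 0.851. The splits are too few for a share under 0.05. An effect of fertilization stays open and untested beyond the design.

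More probe sets than the 2860 given by chance had an unadjusted p under 0.05. A signal difference across whole arrays stays open and cannot be told apart from fertilization. Of 36 spike-in, tag and reporter controls at or above the median level 2.78% had such a p, against 16.1% of rice probe sets. But they stand for 12 targets, of which 1 did, with an exact 95% interval of 0.211% to 38.5%. All probe sets of the spike-ins bioB, bioC, bioD and cre had a higher mean with additional NH4Cl, none at an unadjusted p under 0.05. The groups overlapped in each of them. Array medians were 5.71845 to 5.71846 with additional NH4Cl and 5.71852 to 5.7186 in control, and upper quartiles 6.43731 to 6.43748 and 6.43685 to 6.43712, without overlap, while lower quartiles, 5.45835 to 5.45838 and 5.45837 to 5.45839, and 95th percentiles, 8.4683 to 8.46961 and 8.46844 to 8.4687, overlapped. The splits are too few for a share under 0.05: the real one alone, 1 of 10, gave 6325 probe sets, 4 adjusted calls and 9 lists, against at most 3973, 0 and 7.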
